A study of Mus musculus with 2 samples.

How the data were processed

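ATAC-seq libraries from embryonic day 16.5 mouse kidney were compared as 1 group of 2 biological replicates, numbered as in the labels. The labels say that chromatin was fragmented by tagmentation. The authors deposited peak lists on the mm10 assembly, per the labels. The aligner, the peak caller, their versions and the treatment of cut positions are not given in the sources used here. Each deposited list gives a signal value per summit, the authors' measure of peak height, whose scaling is not given in the sources used here. Each deposited list also gives a −log10 p per summit, which grows with depth. These values belong to the peak and were used to describe, rank or filter peaks within a list, and to match the 2 replicates summit by summit.

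The main list was the authors' conservative list, in which peaks pass a threshold on the irreproducible discovery rate (IDR), a measure of how well ranks repeat between replicates. All of its summits (100.0%) were in the authors' ranked list of the true replicates, and 94.8% were in their optimal list. Each line of a list is a summit, and a region with several summits is listed several times. Replicate values came from lists the authors made for each replicate alone. Reads were not analysed here, so depth is unknown and no counting interval can be given.

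Annotation came from GENCODE vM21 and sequence from the GRCm38 reference, the assembly that mm10 names. 0 main peaks reached past a chromosome end. Of 394 gene entries in the 21 lists, 393 matched 1 of 21938 protein-coding genes, and Ahsp did not. A promoter was the 1000 bp on either side of any annotated start site. Summits elsewhere were distal, and were classed as exonic, intronic or intergenic by GENCODE genes of all types. Tests used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

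Overlap of regions by at least 1 bp and the shares of summits by place were set against 100 circular shifts along each chromosome. Promoters of each list were compared with all other protein-coding genes by a two-sided Fisher's exact test, or by an exact test stratified by CpG class. Distal summits were compared with 10000 random lists matched on decile of the length of sequence nearest to each gene within 100 kb, by a two-sided permutation test. Motif matches within 50 bp of a summit were compared with 2 windows centred 500 bp away. The McNemar exact test set the summit against the upstream window. Ratios used the mean of both windows and were divided by the median of up to 20 permuted motifs. Permuted motifs do not keep CpG pairs together. Benjamini-Hochberg adjustment was made over the 21 lists or the 32 motifs, at a threshold of 0.05. Genes and summits are not independent replicates, and the p-values do not describe the spread between embryos.

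The lists, motifs, tests, main alternatives and the rule for named genes were fixed before the data were examined. The rule took, per list, up to 4 genes with the most distal summits and up to 4 with no promoter summit. It also took the 10 genes with the most distal summits, the genes of the 10 strongest distal summits, and for motifs the 8 highest and 4 lowest corrected ratios.

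Several choices were made after the data were examined. The plan was to take replicate values from the ranked list of true replicates. Its 8 columns for single replicates carry no names and were not used, so each main summit was matched to the nearest summit within 100 bp in each replicate's own ranked list. A motif call was made to need the same side of 1 before and after correction, and 0.5 was added to match counts. Directions were not followed across settings for motifs with under 20 matches (summit matches plus the mean of both flanks), a limit set after the ratios had been seen. The alternatives changed the peak list, the replicate, the promoter window, the start sites, the distance limit, the matching, the overlap rule, the centring and the motif windows, 1 at a time. Alternatives with 1 summit per region or with −log10 p in place of the signal value were added in the same way.

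The steps were tested on simulated data. Of 50 lists of 20 genes made mostly open or mostly closed among 21938 genes, the promoter test called 100.0% in either direction, and 4.0% of unchanged lists. All mostly open lists held the same number of open genes, and so did all mostly closed lists. Each 100.0% is therefore the same outcome repeated. The mostly open lists held more open genes than any list called higher below, so they do not show how often such lists are found. The distal test called 20.0% of 10 lists with a planted 4-fold load, and gave 80.0% of them an unadjusted permutation p under the threshold. It called 0 of 50 unchanged lists. Lists that were not called for distal load can therefore still differ. The motif test called the 3 planted motifs and none of the 29 others in 20000 random sequences. These had the same base content at summits and flanks, and calls used the adjusted p alone. Planted motifs were in a larger share of windows than CTCF or HNF1 in the data. The simulation therefore cannot show how the test does for rare motifs, or where base content differs between summit and flank.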

Results

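Open chromatin was mapped in the kidney of mouse embryos at embryonic day 16.5, when new nephrons are still being made at the edge of the organ. ATAC-seq was used, in which the Tn5 transposase cuts and tags accessible DNA. The series held 1 group of 2 biological replicates, each a pool of male and female embryos of the B6NCrl strain. For replicate 2 the labels gave 41 pooled embryos. There was no second tissue, age or treatment. The comparisons were therefore between the 2 replicates, and within the tissue between fixed gene lists and other genes and between summits and their flanks. The values were the authors' peaks and peak signal values on the mm10 assembly. Reads were not analysed here, so the depth of each library is unknown and no counting interval is given.

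The main list held 66507 summits in 26349 regions on 21 chromosomes and covered 24.9 Mb. Its peaks passed the IDR threshold across both replicates, and its summits and values are those of the pooled replicates. A main summit is therefore not always found in the replicates' own lists. The median region was 917 bp long, and 75.4% of regions had more than 1 summit. In its own thresholded list replicate 1 had 58508 summits in 24104 regions, and replicate 2 had 39231 summits in 16443 regions. The mean was 48870 summits ± 13631 (SD, n = 2). The median signal value was 5.02 in replicate 1 and 4.85 in replicate 2.

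The first comparison asked how far the 2 replicates found the same regions. In replicate 2, 91.6% of regions overlapped a replicate 1 region by at least 1 bp. In replicate 1, 62.2% of regions overlapped a replicate 2 region. Circular shifts of the other replicate's regions along each chromosome gave 1.71% and 1.16% on average. Both shares exceeded all 100 shifts (one-sided permutation p = 0.0099 each, the smallest that 100 shifts can give). With lists of equal length the shares were 82.1% for replicate 2 and 81.4% for replicate 1. Of the main summits, 46975 (70.6%) had a summit within 100 bp in the ranked list of each replicate. With the strongest summit of each region alone the share was 94.8%. Across those 46975 summits the signal values had a Spearman correlation of 0.88 and a Pearson correlation of 0.89 on the log10 scale. The correlation is across summits, which are not independent replicates. The main summits were kept because their ranks repeat between these 2 replicates, so a high correlation is partly built in. With all ranked peaks the Spearman correlation was 0.81, across 64728 summits matched in both replicates. In the main list the median log2 ratio of replicate 2 to replicate 1 was -0.23.

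**Figure D1:**
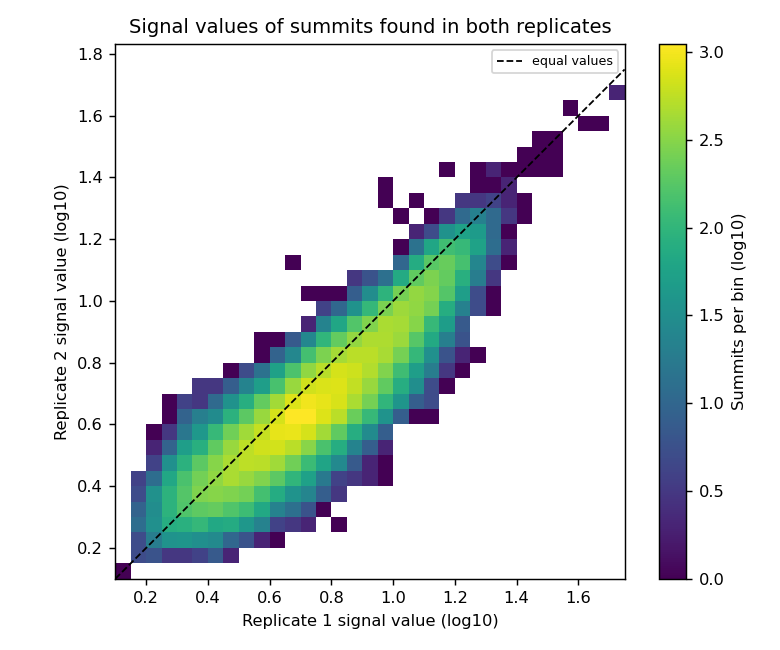
Signal values (log10) of the main summits matched in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, with colour giving the log10 number of summits per bin. Most of the 46975 summits lie below the dashed line of equal values, with a median log2 ratio of -0.23.

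The second comparison asked where in the genome the open sites lay. Promoters, here the 1 kb on each side of an annotated transcription start site, held 62.4% of main summits. Introns held 18.2%, intergenic sequence 17.1% and exons 2.28%. Shifted summits fell in promoters in 6.21% of cases, a 10.1-fold difference, and in introns and intergenic sequence in 39.1% and 51.4%. All 4 shares differed from the shifts (two-sided permutation p = 0.0198 each, the smallest that 100 shifts can give). In the replicates' own lists the promoter share was 71.1% ± 6.61 (SD, n = 2). It was lower in the longer lists, at 38.0% in the list of overlapping peaks and 35.1% in the pooled pseudoreplicated list. With 1 summit per region of the main list it was 53.3%. The share of open sites at promoters therefore depends on the list, though each share was above that of shifted summits. The exon share was below that of shifted summits in the main list, but above it in the list of overlapping peaks, at 3.73%. Of 21938 protein-coding genes, 12996 (59.2%) had a main summit in a promoter.

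The third comparison asked whether promoters of kidney cell types were open more often than those of other genes. Early nephron, podocyte and stroma genes each had 17 of 20 promoters open (85.0%). Each list was above the other protein-coding genes (two-sided Fisher's exact test, adjusted p = 0.0447 over 21 lists). Among early nephron genes, open promoters included those of Hey1 and Jag1, of the Notch pathway, Bmp7, a growth factor of the nephrogenic zone, and Pax8, a transcription factor of the forming nephron. The growth factor gene Fgf8, the Notch target Hes5 and Irx1 had no promoter summit in the main list. Among podocyte genes, Foxc1, Vegfa, Cdkn1c and Ptpro had open promoters, that of Ptpro in neither replicate's own list. Nphs1 and Nphs2, which encode the slit diaphragm proteins nephrin and podocin, and Clic5 had none in the main list. In the list of overlapping peaks Nphs1 and Nphs2 each had 3 promoter summits. Among stroma genes Meis2, Pbx1, Col1a1 and Fat4 had open promoters, and Ecm1, Lum and Ren1, the renin gene, had none in the main list. With overlapping peaks all 20 podocyte genes had open promoters (Fisher's exact test, adjusted p = 0.00681), and early nephron and stroma genes, with 18 of 20 each, did not pass (Fisher's exact test, adjusted p = 0.0888). Against genes of the same promoter CpG class the expected share was 81.0% for early nephron and 80.9% for podocyte genes, so most of their excess was gone (stratified exact test, adjusted p = 0.784 each). For stroma it was 57.5% (stratified exact test, adjusted p = 0.0105), but stroma genes, with 16 of 20 open, did not pass in the optimal list (Fisher's exact test, adjusted p = 0.228). With promoters of 500 bp podocyte and stroma genes did not pass (Fisher's exact test, adjusted p = 0.109 each), nor with 2500 bp early nephron and stroma genes (0.0765 each). No list was called higher by Fisher's exact test with either replicate's own peaks, where 0 lists above the other genes had an unadjusted p under 0.05.

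The promoters of 7 lists were open less often than those of other genes. Macrophage and leukocyte genes had 2 of 20 open, and so did liver genes (Fisher's exact test, adjusted p = 7.2e-05 each). Among them Adgre1, Aif1, C1qa and C1qb of macrophages, and Afp, Ahsg, Apoa2 and Cyp7a1 of liver, had no promoter summit in the main list. Pancreas and intestine genes had 3 of 20 open, and so did pluripotency and germ line genes (Fisher's exact test, adjusted p = 0.000476 each). Members without a promoter summit in the main list included Cela1, Fabp2, Gcg and Hnf4g in the former list and Ddx4, Dppa3, Dppa4 and Dppa5a in the latter. Heart and skeletal muscle genes had 4 of 20 open (Fisher's exact test, adjusted p = 0.00183), and none was at Acta1, Actc1, Myf5 or Myf6. Adrenal cortex genes had 3 of 15 open (Fisher's exact test, adjusted p = 0.00951), and none was at Akr1b7 or the steroid enzyme genes Cyp11a1, Cyp11b1 and Cyp11b2. Erythroid genes had 5 of 19 open (Fisher's exact test, adjusted p = 0.0133), and none was at Alas2, Cldn13, Epb42 or Ermap. Absence from the main list is not absence of signal: in the list of overlapping peaks Afp, Cela1, Hnf4g and Myf6 had 3 promoter summits each, Actc1 and Epb42 had 2 and Myf5 had 1. All 7 lists were also lower with each replicate's own peaks. Against genes of the same promoter CpG class, 3 lists were lower: pancreas and intestine, pluripotency and germ line, and forebrain. The expected share was then 31.1% for erythroid, 33.0% for adrenal cortex, 37.5% for heart and skeletal muscle, 30.8% for macrophage and leukocyte and 27.5% for liver genes, and these 5 no longer passed (stratified exact test, adjusted p = 0.784, 0.558, 0.127, 0.0977 and 0.127). With the pooled pseudoreplicated peaks, 3 lists were lower: macrophage and leukocyte, liver, and pluripotency and germ line. Heart and skeletal muscle genes, with 11 of 20 open, did not pass with overlapping peaks either (Fisher's exact test, adjusted p = 0.296).

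The other 11 lists did not pass the threshold in the main list, but some did in other lists. With overlapping peaks 19 of 20 nephron progenitor genes, 19 of 20 ureteric bud and collecting duct genes and 25 of 27 Hox genes of groups 1 to 9 were open (Fisher's exact test, adjusted p = 0.0266 each). With pooled pseudoreplicated peaks, 20 of 20 nephron progenitor genes and 26 of 27 of those Hox genes were (Fisher's exact test, adjusted p = 0.00837 each). With the stronger 50% of summits the same Hox list was lower, at 7 of 27 (Fisher's exact test, adjusted p = 0.00496), and so were forebrain genes, at 4 of 20 (Fisher's exact test, adjusted p = 0.00423). With promoters of 500 bp, neuron and neural crest genes were lower, at 6 of 20 (Fisher's exact test, adjusted p = 0.0316). The values that follow are of the main list. In it, nephron progenitor genes had 13 of 20 promoters open. The progenitor regulators Six2 and Pax2 had an open promoter, and Gdnf, Hoxa11, Tmem100 and Crym had no promoter summit. Ureteric bud and collecting duct genes had 12 of 20 open, among them Wnt11, Etv4, Etv5 and Tfcp2l1, with Wnt11 not in replicate 2's own list. The water channel gene Aqp2, the vasopressin receptor gene Avpr2, Elf5 and Hoxb7 had none. Loop of Henle and distal tubule genes had 11 of 20 open, including Esrrg, Mecom and Trpm6, the last 2 not in replicate 2's own list. The salt transporter genes Slc12a1 and Slc12a3, Klk1 and Pvalb had neither a promoter nor a distal summit. Proximal tubule genes had 10 of 20 open. The endocytic receptor gene Lrp2 had an open promoter, and Amn, Slc5a2, Aldob and Cubn had none. Endothelium genes had 9 of 20 open, with none at Plvap, Robo4, Sox7 and Sox18. Neuron and neural crest genes also had 9 of 20 open, with none at Dbh, Foxd3, Neurod1 and Phox2b. Forebrain genes had 8 of 20 open, with none at Eomes, Fezf2, Foxg1 and Gad1. Lung genes also had 8 of 20 open, with none at Ager, Lamp3, Nkx2-1 and Sftpa1. Hox genes of paralogue groups 1 to 9 had 16 of 27 open, those of groups 10 and 11 had 4 of 6, and those of groups 12 and 13 had 2 of 6. Hoxa2, Hoxa6, Hoxb5, Hoxb6, Hoxa11, Hoxc11, Hoxa13, Hoxb13, Hoxc12 and Hoxd12 were among the members with none. In the list of overlapping peaks many of these had promoter summits, among them 6 at Hoxa11, 5 at Foxd3, 4 each at Nkx2-1 and Hoxd12, 3 each at Gdnf, Neurod1 and Eomes, 2 at Gad1 and 1 at Foxg1. In that list 17 of 20 loop of Henle and distal tubule genes, 17 of 20 endothelium genes and 6 of 6 Hox genes of groups 10 and 11 were open. Some members named above for those lists, and for the ureteric bud list, therefore had promoter summits there.

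**Figure D2:**
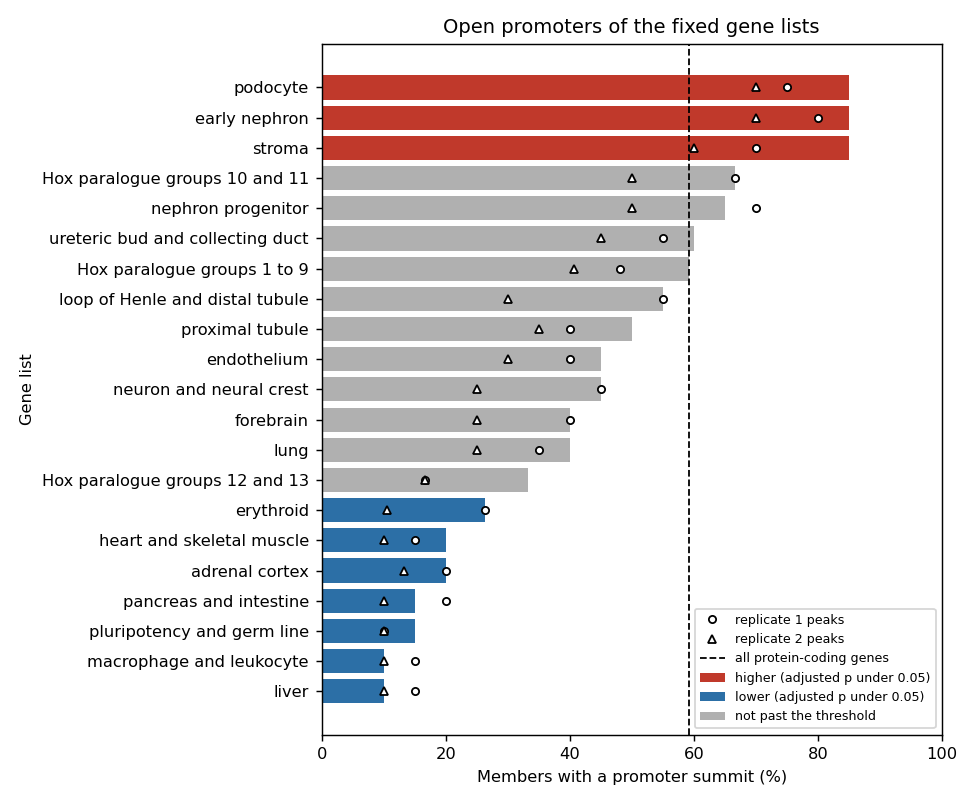
Percentage of each list's genes with a promoter summit in the main list (bars), in replicate 1's own peaks (circles) and in replicate 2's own peaks (triangles), with all protein-coding genes at 59.2% (dashed line). The 3 red bars, at 85.0%, passed the test above the other genes, and the 7 blue bars passed it below them.

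The fourth comparison asked whether genes of each list had more distal open sites nearby than random genes with as much surrounding sequence. A distal summit, over 1 kb from every start site, was given to the gene with the nearest start site within 100 kb. Early nephron genes had a mean of 4.25 distal summits, against 1.79 ± 0.678 (SD of 10000 matched random lists). Podocyte genes had 4.05 against 1.73 ± 0.667, and ureteric bud and collecting duct genes had 2.75 against 1.04 ± 0.473. These 3 lists and Hox groups 1 to 9, with 0.926 against 0.254 ± 0.169, had an adjusted permutation p of 0.0315. Stroma genes had 4.00 against 1.83 ± 0.685 (adjusted permutation p = 0.0370). No list was called with either replicate's own peaks, with 1 summit counted per region, or when random genes were also matched on CpG class or on having a promoter peak. By the permutation test with replicate 1's own peaks 6 lists had an unadjusted p under 0.05, and with replicate 2's own peaks 7. Across those 5 settings the ratio to matched lists stayed above 1 in all 5 lists, with the lowest at 1.84.

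For single genes, counts in brackets are those in replicate 1's and replicate 2's own lists, and most are lower than in the main list. Among early nephron genes Hey1 had 15 distal summits (10 and 8), Bmp7 had 13 (10 and 4), Jag1 had 12 (8 and 3) and Pax8 had 9 (14 and 8). The replicates' own lists gave Hey1 9.0 ± 1.41 (SD, n = 2). Its strongest summit lay in an intergenic region at chromosome 3, 8717057 to 8718442, which was 50475 bp from the nearest Hey1 start site. The signal value there was 8.87 ± 0.780 (SD, n = 2). Among podocyte genes Foxc1 had 13 (4 and 3), Vegfa 11 (2 and 5), Cdkn1c 7 (3 and 3) and Ptpro 7 (4 and 4) distal summits. The strongest of Foxc1 was intergenic, at chromosome 13, 31760117 to 31761088, with a signal value of 7.37 ± 0.296 (SD, n = 2). Among ureteric bud and collecting duct genes Wnt11, a ligand of the bud tips, had 12 (7 and 8), Etv5 had 7 (4 and 5) and Tfcp2l1 had 6 (4 and 5). Etv4 had 4, none of them in either replicate's own list. The strongest of Wnt11 lay over an exon at chromosome 7, 98887759 to 98888449, with a signal value of 5.76 ± 2.29 (SD, n = 2). Among stroma genes Meis2 had 18 (9 and 3), Pbx1 had 11 (13 and 3), Col1a1 had 9 (3 and 7) and Fat4 had 8 (4 and 4). The strongest of Meis2 was intronic, at chromosome 2, 115979720 to 115980681, with a signal value of 6.47 ± 0.825 (SD, n = 2). Among Hox genes of groups 1 to 9, Hoxc4 had 5 (4 and 6), and Hoxb1 (1 and 0), Hoxb4 (2 and 1) and Hoxd3 (1 and 3) had 4 each. The strongest of Hoxc4 was intergenic, at chromosome 15, 103060012 to 103061749, with a signal value of 8.61 ± 0.710 (SD, n = 2).

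Nephron progenitor genes had 3.30 distal summits against 1.78 ± 0.678 and did not pass the threshold in the main list (adjusted permutation p = 0.155). They did with overlapping peaks, pooled peaks and a limit of 500 kb, at ratios of 1.89, 1.85 and 2.62 (adjusted permutation p = 0.0420, 0.0273 and 0.0105). In that list Pax2 had 13 (7 and 4), Uncx 11 (6 and 6), Dpf3 7 (2 and 1) and Six2 7 (6 and 5). The strongest of Pax2 was intronic, at chromosome 19, 44834177 to 44835466, with a signal value of 5.60 ± 0.0206 (SD, n = 2). Loop of Henle and distal tubule genes had 2.70 against 1.38 ± 0.577, led by Esrrg with 14 (7 and 5) and Mecom with 12 (12 and 4). The strongest of Esrrg was a promoter summit at chromosome 1, 187997529 to 187998355. Proximal tubule genes had 1.95 against 1.05 ± 0.482, led by Cubn, a receptor of albumin uptake, with 7 (9 and 5) and Lrp2 with 5 (3 and 1). The strongest of Cubn was intronic, at chromosome 2, 13371828 to 13373119, with a signal value of 11.6 ± 0.842 (SD, n = 2). Endothelium genes had 2.35 against 1.27 ± 0.544, led by Flt1, a VEGF receptor gene, with 10 (6 and 4). Its strongest summit was exonic, at chromosome 5, 147645125 to 147645617. The other 12 lists had ratios from 0 (Hox groups 12 and 13) to 2.76 (Hox groups 10 and 11), and none of them passed the threshold in any setting.

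Members of the remaining lists, of other cell types, other organs and Hox genes, also had distal summits. Fcgr3, an Fc receptor gene, had 14 (8 and 5), Syt1 had 10 (8 and 2), Wnt7b had 9 (6 and 9), Prdm1 had 9 (6 and 5), Ttr had 8 (8 and 1), Sptb had 6 (1 and 0) and Dlx2 had 6 (5 and 0). The remaining leaders had fewer: Cpa1 (1 and 2) and Ryr2 (2 and 0) had 4 each, Scarb1 had 3 (0 and 0) and Hoxc11 had 2 (0 and 0). The strongest summits lay at chromosome 1, 171044215 to 171045214 for Fcgr3 (intergenic) and chromosome 10, 109010455 to 109012081 for Syt1 (promoter). For Wnt7b it lay at chromosome 15, 85634320 to 85635342 (intergenic), and for Prdm1 at chromosome 10, 44529171 to 44530068 (intergenic). For Ttr it was at chromosome 18, 20642906 to 20643542 (intron), and for Sptb at chromosome 12, 76709267 to 76710997 (promoter). For Dlx2 it was at chromosome 2, 71643995 to 71644490 (intergenic), and for Cpa1 at chromosome 6, 30636180 to 30636740 (intergenic). For Ryr2 it was at chromosome 13, 12105892 to 12107338 (promoter), and for Scarb1 at chromosome 5, 125283573 to 125284571 (promoter). For Hoxc11 it was at chromosome 15, 102959687 to 102960211 (intergenic).

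**Figure D3:**
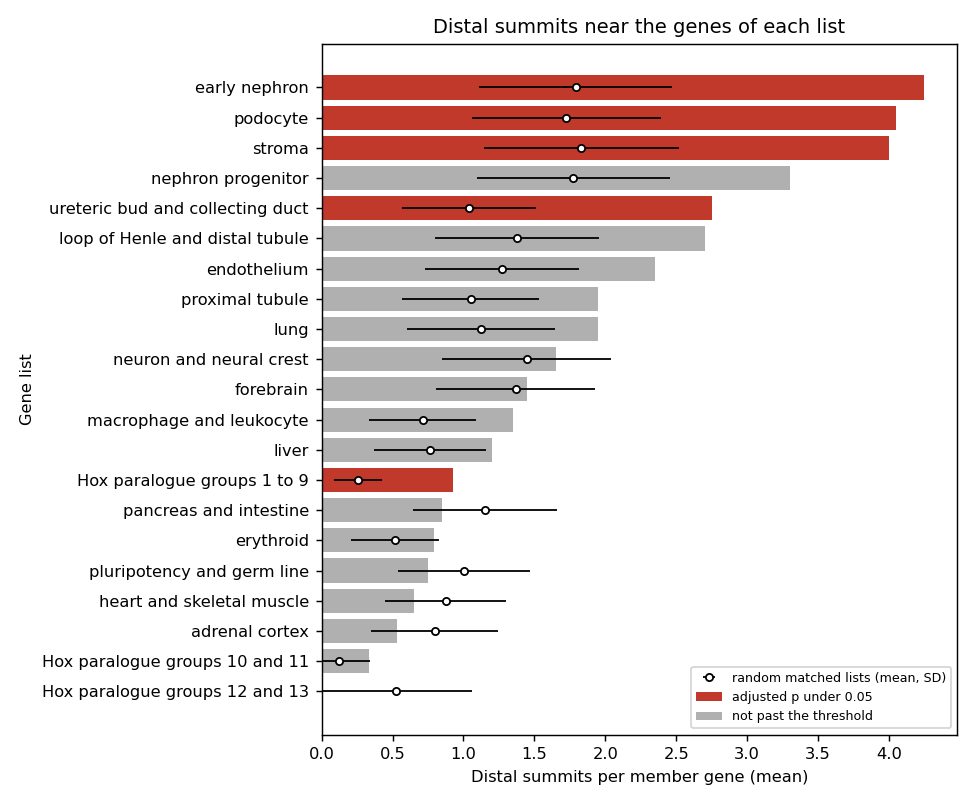
Mean number of distal summits per gene of each list (bars), with the mean and SD of 10000 random lists matched on the length of surrounding sequence (circles and lines, truncated at 0). The 5 red bars passed the test, and early nephron genes had the highest mean, 4.25 against 1.79.

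Genome-wide, the protein-coding genes with the most distal summits were Gse1 with 30 (30 and 24), Bcor with 29 (14 and 9), Pkdcc with 27 (19 and 16) and 1700001O22Rik with 26 (18 and 11). Tenm4 (24 and 11), Tns3 (19 and 10), Maml3 (18 and 15) and Cstad (14 and 14) had 25 each, Ncor2 had 24 (17 and 14) and Pde4d had 22 (16 and 9). The replicates' own lists gave Gse1 27.0 ± 4.24 and Bcor 11.5 ± 3.54 (SD, n = 2). The 10 distal summits of highest signal value lay in 9 regions and were given to Abcb11, Pak3, Gm5426, Frmd4a and Hic2, or to no gene within 100 kb. The strongest, at chromosome 2, 69355469 to 69355735, was intergenic and had a signal value of 51.9 ± 5.85 (SD, n = 2). Of those 10 summits, 9 lay mostly in sequence with another copy on the chromosomes or in the mitochondrial genome. Sequence found in the mitochondrial genome was in 6.

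The fifth comparison asked whether any list's peaks differed together between the 2 pools. After centring on all peaks, the median log2 ratio of replicate 2 to replicate 1 was 0.11 for nephron progenitor genes and 0.13 for Hox groups 1 to 9. These medians lay at percentiles 97.7 and 97.8 of 10000 random lists matched on signal. The other 18 lists with enough matched peaks lay inside the central 95% of random lists, a limit that about 1 of 20 lists passes by chance. With 1 library for each pool, these are descriptions of the libraries and no test was made. With promoter peaks alone, 0 lists lay outside that range. With distal peaks alone nephron progenitor genes, at percentile 97.6, lay outside it, and Hox groups 1 to 9, at 77.2, did not. With −log10 p the Hox list, at 99.1, lay outside it, and nephron progenitor genes, at 92.85, did not. With all ranked peaks the Hox list, at 97.2, was inside and nephron progenitor genes, at 99.1, outside.

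The sixth comparison asked which sequence motifs were concentrated at summits. At distal summits 13 of 32 motifs were more frequent than in the flanks and 0 were less frequent. At promoter summits 9 were more frequent and 1 less frequent. These calls needed a McNemar exact test against the upstream flank and a ratio on the same side of 1 before and after correction by permuted motifs. By the exact test alone there were 14 distal and 18 promoter calls. The test alone added GATA at distal summits, and TEAD, GATA, SOX, TFAP2, TCF/LEF, FOX, RUNX and MEF2 at promoter summits. Their ratios lay on opposite sides of 1 before and after correction, a rule set after the data were examined. At distal summits the CTCF motif (CCASYAGRKGGC), of the insulator protein, was in 1.39% of windows and 0.168% of flanks, with a corrected ratio of 5.11 (McNemar exact test, adjusted p = 6.94e-60). The HNF1 motif (GTTAATNATTAA), of factors of the tubule epithelium, was in 0.0801% of windows (20 matches) and 0.0200% of flanks, a ratio of 3.73 that correction raised to 11.9 (McNemar exact test, adjusted p = 0.0486). The PBX-HOX motif, in 26 windows, had a ratio of 3.53 before and 5.57 after correction (McNemar exact test, adjusted p = 0.0174). The TEAD motif (RCATTCCW) was in 3.48% of windows and 1.86% of flanks, with a corrected ratio of 2.53 (McNemar exact test, adjusted p = 2.23e-28). Without replicate 1 neither HNF1 nor PBX-HOX passed (McNemar exact test, adjusted p = 0.603 and 0.140). MEF2 at 2.54 and POU3F at 1.99 did not pass, nor did EBF at 0.893 and ESRR at 0.768. Before correction POU3F stood at 0.660 and EBF at 1.42, on the other side of 1. ESRR was less frequent with flanks 1000 bp away, at 0.664, and without replicate 1, at 0.404 (McNemar exact test, adjusted p = 0.0168 and 0.0369). REST, RFX, PAX2/5/8 and HOX10/11 had under 20 matches, counting summits plus the mean of both flanks, and no direction was read from them in the main list. With overlapping and pooled peaks REST stood at 15.8 and 17.8 (McNemar exact test, adjusted p = 4.10e-08 and 2.46e-09), and RFX at 2.5 and 3.77 (McNemar exact test, adjusted p = 0.00393 and 1.86e-05).

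At promoter summits REST, a repressor of neuronal genes, had a corrected ratio of 4.63 from 18 matches (McNemar exact test, adjusted p = 0.00927), but did not pass without replicate 1 (0.212). The ETS motif (ACCGGAAGT) was in 0.518% of windows and 0.134% of flanks, with a corrected ratio of 3.93 (McNemar exact test, adjusted p = 8.11e-24). ESRR was less frequent, with a corrected ratio of 0.665 (McNemar exact test, adjusted p = 0.00358). Before correction POU3F, the POU octamer and EBF stood at 0.511, 0.873 and 1.15, on the other side of 1 from their corrected ratios. At corrected ratios of 2.45, 2.34 and 0.738 these 3 did not pass. With 1 summit per region the octamer, at 7.63, and EBF, at 0.264, did (McNemar exact test, adjusted p = 0.000885 and 0.0284). PBX-HOX, PAX2/5/8, HNF1, RFX, HOX10/11 and the NFI full site had under 20 matches by the same count. Neighbouring summits share sequence, so these p-values are too small. With 1 summit per region, 14 distal motifs and 10 promoter motifs were more frequent.

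**Figure D4:**
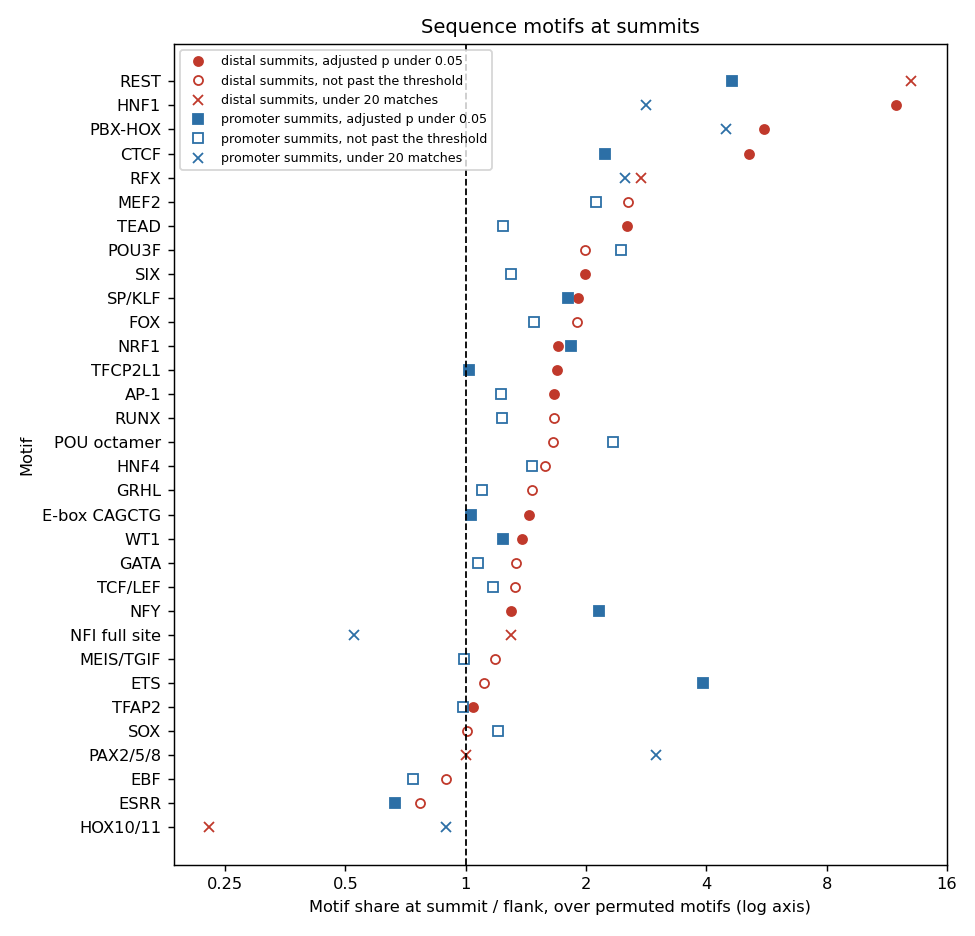
Share of windows at summits with each of 32 motifs over the share in flanks, divided by the same ratio for permuted motifs (log axis), for distal (red) and promoter (blue) summits. Filled symbols passed the McNemar exact test and had ratios in the same direction before and after division by that of permuted motifs. Motifs that passed the exact test alone are not filled. Crosses mark motifs with under 20 matches (summits plus the mean of both flanks). CTCF stood at 5.11 in distal summits and ETS at 3.93 in promoter summits.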

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

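The tests in this part, apart from a count by region, were written down before their results were seen. In the authors' ranked list of true replicates, 226 summits in 97 regions passed the IDR threshold but were absent from the main list. These summits entered no value of the main list, but those on the 21 chromosomes were part of the setting with all ranked peaks. Of the 226 summits, 61 lay on sequences outside the 21 chromosomes. The strongest region, at chromosome 1, 24611582 to 24616165, had 16 summits and reached a −log10 p of 10861.

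A candidate explanation of the chromosome 1 region is mitochondrial DNA aligned to a nuclear copy. Of its 24-base sequences, 99.1% occur in the mitochondrial genome, as that explanation needs. For the absent summits as a whole, copies elsewhere in the genome were tested. On the chromosomes, 45.5% of absent summits had at least 50% of their 24-base sequences more than once, against 3.20% of 1000 main summits (Fisher's exact p = 5.25e-46). The absent summits here include the 16 of the chromosome 1 region, where 99.1% of the sequence is repeated. Summits of 1 region are not independent, so this p is too small. The share was above the main list but below the 50% of summits that was set in advance. Counted by region, since summits of 1 region share sequence, 54.3% had at least 1 such summit. This count was not set in advance and was not made for the main list. For the absent summits on the chromosomes the cause stays open, with repeated sequence not excluded. The 61 summits on other sequences were not tested for copies, and the main list holds the 21 chromosomes alone. No biological explanation was tested.

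The 10 distal main summits of highest signal value were weighed in the same way. Repeated sequence may account for them, since 9 of 10 had at least 50% of their 24-base sequences more than once. Copies were counted over the 21 chromosomes and the mitochondrial genome together, so this count overlaps with the mitochondrial one. The summits at chromosome 2, 69355602, and chromosome 10, 96077663, had a median of 2 copies, with 100% and 96.2% of these sequences mitochondrial. Mitochondrial DNA may account for part of the 10 summits, since 6 of 10 had a mitochondrial 24-base sequence. Among all 66507 main summits 21 had one. Of the 10, the 2 with the highest −log10 p, up to 9052, shared 1 intergenic region at chromosome 12, 97061368 to 97061856. No biological explanation was tested, and a site that is both repeated and open is not excluded.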

How the results depend on the processing

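Under 31 settings 842 values were recomputed, and 123 of them answered a comparison. Of these, 92 kept their direction and side of the threshold or stayed within their limits, and 31 moved. Of the others, 562 did so too, 76 fell short of the threshold, 15 newly passed it, 3 moved and 63 turned direction. Counts of lists or motifs were judged by size alone, and members can differ, as for open promoters with overlapping peaks. Apart from centring, the cause was not tested. The settings with 1 summit per region or with −log10 p were chosen after seeing the data. Below, open promoters are the list's percentage minus that of other genes, distal load is the ratio to matched lists, and motifs are corrected ratios. Library depth is unknown, so its effect on the difference between the replicates' lists cannot be given. No paired analysis was possible because there was 1 group.

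The overlap of regions and the promoter, intron and intergenic shares kept their direction and their side of the threshold in every setting run for them. More frequent motifs numbered 11 to 18 in distal and 7 to 10 in promoter summits. The signal correlation, 0.88 in the main list, was 0.813 with all ranked peaks, 0.873 with −log10 p and 0.851 with 1 summit per region. With 1 summit per region, 0 lists were higher for distal load, neuron and neural crest genes had a distal ratio of 0.914, and 2 promoter motifs were less frequent. The optimal list gave 1 list higher for distal load, open promoters of 3.47 for proximal tubule and 3.47 for loop of Henle and distal tubule, and a distal ratio of 0.968 for neuron and neural crest.

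With the overlapping peaks the exon share was 3.73%, above shifted summits. Open promoters were 6.16 for proximal tubule, 16.2 for loop of Henle and distal tubule, 16.2 for endothelium, 6.16 for neuron and neural crest and 11.2 for forebrain. Distal ratios were 0.674 for neuron and neural crest, 0.985 for liver and 0.909 for forebrain, and the distal ESRR motif was at 1.14. With the pooled pseudoreplicated peaks the exon share was 3.73%, and 3 lists had fewer open promoters. Open promoters were 10.3 for proximal tubule, 20.3 for loop of Henle and distal tubule, 15.3 for endothelium, 5.25 for neuron and neural crest and 15.3 for forebrain. The distal ratio of neuron and neural crest was 0.828, and the distal ESRR motif was at 1.07.

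With the stronger 50% of summits by signal value, 0 lists had more open promoters and 1 list was higher for distal load. Open promoters were -1.28 for ureteric bud and collecting duct, -30.4 for Hox groups 1 to 9 and -22.9 for Hox groups 10 and 11. Distal ratios were 0.927 for neuron and neural crest and 0 for Hox groups 10 and 11, and 2 promoter motifs were less frequent. With promoters of 500 bp, the exon share was 4.11%, 1 list had more open promoters and 2 lists were higher for distal load. Open promoters were then -3.42 for ureteric bud and collecting duct and -10.3 for Hox groups 1 to 9. With promoters of 2500 bp, 1 list had more open promoters, open promoters of proximal tubule were 4.05 and the distal ratio of forebrain was 0.890. Start sites of protein-coding transcripts alone gave an exon share of 4.19%, which no longer differed from shifted summits (permutation p = 0.455). They gave open promoters of -6.27 for Hox groups 1 to 9, and distal ratios of 0.776 for neuron and neural crest, 1.13 for adrenal cortex and 0.946 for forebrain.

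Within the same CpG class, 1 list had more and 3 lists had fewer open promoters. Early nephron, podocyte and erythroid lists came close to the expected share. Open promoters were -5.92 for nephron progenitor, 15.9 for proximal tubule, 4.16 for loop of Henle and distal tubule, -14.4 for Hox groups 1 to 9 and -13.2 for Hox groups 10 and 11. Matching distal load also on CpG class left 0 lists higher, with forebrain at 0.923. Matching also on a promoter peak left 0 lists higher, with pancreas and intestine at 1.03. With a limit of 50 kb neuron and neural crest was at 0.971, and with 500 kb forebrain was at 0.747.

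For the replicate difference, leaving out centring moves every list and random list by -0.23. The uncentred medians of -0.12 for nephron progenitor and -0.11 for Hox groups 1 to 9, counted above as turned, therefore kept percentiles of 97.7 and 97.8 and say nothing about stability. The number of lists outside the central 95% was 0 with promoter peaks, 1 with distal peaks and 1 with −log10 p. Only these 2 lists were followed across settings. With all ranked peaks the number was again 2, but the lists were nephron progenitor and early nephron. For motifs, flanks centred 1000 bp away gave 1 less frequent distal motif, and a window of 25 bp gave 0 less frequent promoter motifs. Without correction by permuted motifs, 1 distal and 8 promoter motifs were less frequent. POU3F was then at 0.660 and EBF at 1.42 in distal summits, and POU3F at 0.511, the POU octamer at 0.873 and EBF at 1.15 in promoter summits.

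With each replicate left out in turn, the lists with more open promoters and the lists higher for distal load both numbered from 0 to 0. Open promoters ranged from -0.826 to 11.7 for nephron progenitor, from -5.83 to -3.34 for ureteric bud and collecting duct, from -10.2 to -10.1 for Hox groups 1 to 9 and from -0.825 to 8.34 for Hox groups 10 and 11. Distal ratios ranged from 0.827 to 1.91 for liver, from 0.527 to 1.42 for heart and skeletal muscle and from 0 to 0 for Hox groups 10 and 11. Less frequent motifs ranged from 0 to 1 in distal and from 2 to 2 in promoter summits, and distal POU3F from 0.674 to 1.30.

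Distal counts of single named genes were followed apart from these values: of 162 genes, the number that moved by more than the replicates' SD was 123 with pooled peaks, 108 with overlapping peaks, 75 with 1 summit per region, 72 without replicate 1, 71 with the stronger 50% of summits, 69 without replicate 2 and 17 to 41 in the other settings. These counts also leave out 4 distal and 6 promoter motifs with under 20 matches, a limit set after their ratios had been seen. Their 110 values under alternatives were the same in 85 cases, newly passed the threshold in 6 and were counted as turned in 19. Of those 19, 6 began or ended at exactly 1, so they gained or lost a direction and did not reverse it. The 6 that newly passed were distal REST at 15 with the optimal list, 15.8 with overlapping peaks, 17.8 with pooled peaks and 7.5 without replicate 2, and distal RFX at 2.5 with overlapping and 3.77 with pooled peaks. Values counted as turned in distal summits, where PAX2/5/8 stood at 1 in the main list, were PAX2/5/8 at 3.0 and HOX10/11 at 1.13 with overlapping peaks, PAX2/5/8 at 5.0 and HOX10/11 at 1.33 with pooled peaks, and HOX10/11 at 1.01 in windows of 100 bp. Those of HOX10/11 in promoter summits were 2.68 with the stronger 50% of summits, 1.84 in windows of 100 bp, 2.21 with flanks 1000 bp away and 1.70 with 1 summit per region. In promoter summits PAX2/5/8 was at 1.0 in windows of 25 bp, the NFI full site at 1.85 in windows of 100 bp and HNF1 at 1.0 without correction. With each replicate left out in turn, distal ratios ranged from 0.5 to 2.33 for RFX, 1.0 to 3.0 for PAX2/5/8 and 0.545 to 1.56 for HOX10/11. Promoter ratios ranged from 1.0 to 3.0 for PAX2/5/8, 1.14 to 1.47 for HOX10/11 and 0.667 to 1.17 for the NFI full site. By the McNemar exact test alone, calls numbered 14 distal and 18 promoter motifs in place of 13 and 10.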

Other observations

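Gene families chosen by symbol after the data were seen showed a wide range of open promoters. They were compared with all other protein-coding genes and not with genes of the same promoter CpG class. Repeated sequence within these families was not examined. Of 1135 olfactory receptor genes 4 had a promoter summit (Olfr15, Olfr94, Olfr214 and Olfr658), and of 331 vomeronasal receptor genes 1 did (Fisher's exact test, adjusted p = 1.53e-127). Cytochrome P450 genes, many of them used in liver, had 16 of 96 open (Fisher's exact test, adjusted p = 6.80e-17), and protocadherin genes had 12 of 69 (Fisher's exact test, adjusted p = 3.25e-12). Mitochondrial ribosomal protein genes had 76 of 78 open (Fisher's exact test, adjusted p = 1.27e-14) and semaphorin genes 19 of 20 (Fisher's exact test, adjusted p = 0.00147). Genes with symbols starting in Rpl or Rps and a digit had 87 of 98 open (Fisher's exact test, adjusted p = 3.54e-10). That match takes cytosolic ribosomal protein genes but also others, such as the kinase genes named Rps6k.

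Among 25 families, 4 had fewer distal summits than matched random genes. The ratio was 0.0934 for olfactory and 0.0781 for vomeronasal receptors (adjusted permutation p = 0.00250 each, also with each replicate's own peaks). It was 0.0630 for keratin-associated proteins (adjusted permutation p = 0.0212) and 0.517 for cytochromes P450 (adjusted permutation p = 0.0408). With the replicates' own peaks the former did not pass, and the latter passed in replicate 1 alone (adjusted permutation p = 0.0183) and not in replicate 2 (0.251). Forkhead and Wnt genes had more distal summits than matched random genes. Forkhead genes had 2.57 against 1.27 ± 0.366 (adjusted permutation p = 0.0212), and Wnt genes had 2.47 against 0.936 ± 0.430 (adjusted permutation p = 0.0310). With the replicates' own peaks neither family passed the threshold, though the ratios of 2.02 and 2.64 in the main list were then 1.75 and 1.91 for forkhead and 2.40 and 3.19 for Wnt genes. In replicates 1 and 2 the adjusted permutation p was 0.0864 and 0.210 for forkhead genes, and 0.0864 and 0.110 for Wnt genes. With overlapping peaks both passed, at 1.67 and 2.36 (adjusted permutation p = 0.0183 and 0.00200). Their promoters were open in the main list in 22 of 44 and 9 of 19 genes. For Wnt genes the count was 6 with replicate 1's own peaks, 2 with replicate 2's and 15 with overlapping peaks.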
